A study of Homo sapiens with 8 samples.

How the data were processed

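Total RNA of 8 SEM samples was labelled with biotin and hybridised to Illumina bead arrays, per the labels. GenomeStudio was used, per the submitters' processing notes, which give no version. The background correction and the normalization were not given in the sources used here. The deposited values were taken as natural log expression values, a unit inferred from the numbers and not stated by the authors. As natural logs the brightest probe corresponds to a linear intensity of 38664, and as logs to base 2 it would be 1512. Near zero, the share of values per unit of linear intensity stayed about level for base e (1.77, 2.64 and 2.23% per unit in 3 successive ranges), as background-subtracted noise would give, whereas it climbed for base 2 (1.84, 4.16 and 5.54%) and dropped for base 10 (2.54, 0.707 and 0.0790%). The 8 arrays share the same distribution, with medians within 0.00216 of each other, which points to normalization over both array versions together before deposit. Between 28.5% and 28.8% of the 39421 probes per array have the entry Null, which was treated as missing. Of all probes, 14751 have a value on all 8 arrays. For 134 probes there were values on all siCtrl arrays and on no siMLL/AF4 array, and for 159 probes the reverse.

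The values were divided by the natural log of 2 and used as normalized by the authors. Both tables list the same 39421 probe identifiers. The platform annotation gave 27210 probes 1 gene symbol and 8 probes several, and 12203 probes are not listed in it. All columns mapped to a sample (0 unmapped). Symbols were updated through the Entrez identifier with a table of RefSeq gene names, in which 27177 probes matched. Probes with several symbols or none were not tested. A probe was tested when it had a value on all arrays of the fit and a mean at or above the median probe within each array version. The probe with the highest mean stood for a gene. As the values proved to be logs with missing entries, the offset planned for linear values was not needed in the main analysis.

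Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjusted p-values at a threshold of 0.05. The knock-down model held time point as a block and treatment, on the 6 siRNA arrays, with 2 residual degrees of freedom. The change of the effect with day added the product of treatment and day. The change with day used the 4 siRNA arrays of the older version, with treatment as a block. The siCtrl against MOCK model used all 8 arrays with time point as a block. Differences on single days were not tested. For these, the median of each list was ranked among 10000 random lists of the same size matched on mean expression. The 27 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. The lists of myeloid, T and NK cell and erythroid markers stand for cell types other than a B-cell precursor. The tests, lists, alternatives and rule for naming genes were set before the data were examined, apart from the additions named below.

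The text names all KMT2A and AFF1 probes and, for the knock-down, the 12 genes with the largest positive and the 12 with the largest negative change among those that passed with 1 sign on all days. Where fewer passed, the places were filled by the largest minimum difference. Up to 4 members per list were named by size of change, and all tested members of the HOXA and MLL/AF4 target lists could be named. For each other comparison the 5 highest and 5 lowest genes were named. Genes without a symbol of their own were skipped.

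Alternatives covered quantile normalization within array version, a common median, offsets of 1 and 64, a floor at the 25th percentile, no filter, a filter at the 70th percentile, the mean of probes, a trended robust variance, leaving out each time point, no block, MOCK arrays in the estimate of spread, the mean of siCtrl and MOCK as control, and other set tests. Added after seeing the data were the list tests of all comparisons other than the knock-down averaged over days, an offset of 16, testing probes with Null entries at the floor, the stricter filter joined with the trended robust variance, and further control arrays or set tests for the lists and the target probes. Each model was tested on simulated data with 200 changed genes, in 10 simulations. For the knock-down model on 9096 genes, changes of 1, 2 and 3 on the log2 scale were recovered in 0.00%, 22.7% and 71.8% of cases, with 3.20 unchanged genes called on average. For siCtrl against MOCK on 8886 genes the shares were 0.746%, 44.8% and 77.7%. A list of 20 genes shifted by 1 was called in 10 of 10 simulations of each model. The noise was drawn independently for each gene, and most lists called in the real data shifted by less than 1. The simulations therefore do not show how camera behaves on lists with correlated members or smaller shifts. Figures were drawn with matplotlib 3.10.9.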

Results

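Genome-wide expression was measured on Illumina bead arrays in SEM, an established cell line of B-cell precursor acute lymphoblastic leukaemia that carries the MLL/AF4 fusion gene. The cells were electroporated up to 3 times, 2 days apart, with siRNA against the fusion transcript (siMLL/AF4) or with control siRNA (siCtrl), and were harvested on day 2, 4 and 6. Cells pulsed without siRNA (MOCK) were taken on day 2 and day 4. Each treatment and day had 1 array, 8 in all. Effects were therefore tested as averages over the 3 days, and the p-values measure the spread between days and arrays, not between independent cultures. The number of arrays limits the precision of every value below. The day 6 pair was hybridised to a newer array version than the other 6 arrays, so each difference was taken within a day. Values are given as log2, converted from deposited values that were inferred to be natural logs. If they were logs to base 2 instead, every log2 level and difference below would be 0.693 times as large, except those with an offset. The p-values of fits without an offset do not depend on the base. Counts at 2-fold and all results with an offset do. The siMLL/AF4 array of day 6 correlated least with the 6 older arrays, with a median Spearman correlation across probes of 0.831, against 0.873 for siCtrl on day 6 and 0.911 to 0.921 among the older arrays (probes are not independent replicates).

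The first question was whether probes of the genes joined in the fusion followed the labels. KMT2A (MLL), a histone methyltransferase gene, was lower with siMLL/AF4 than with siCtrl on all 3 days, by -0.52 ± 0.03 (SD, n = 3 days). AFF1 (AF4), a gene of the transcription elongation machinery, was lower by -1.25 ± 0.76 (SD, n = 3) at probe ILMN_2129015 and by -1.24 ± 0.83 (SD, n = 3) at probe ILMN_1673119. The first AFF1 probe differed by -2.02, -1.21 and -0.51 on day 2, 4 and 6, while the second differed by -0.35, -1.37 and -2.00, so their order over the days was opposite. Neither gene passed the test over all genes (limma, adjusted p = 0.681 for KMT2A and 0.586 for AFF1). Against MOCK, KMT2A differed by 0.057 and 0.039 with siMLL/AF4 on day 2 and day 4, whereas siCtrl lay above MOCK by 0.55 and 0.59. The AFF1 probes in siCtrl lay above MOCK by 1.32 to 1.49, and siMLL/AF4 differed from MOCK by between -0.60 and 1.14. The siCtrl arrays thus serve both contrasts. These probes lie in genes that are also transcribed outside the fusion, so they check the labels only in part.

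**Figure D1:**
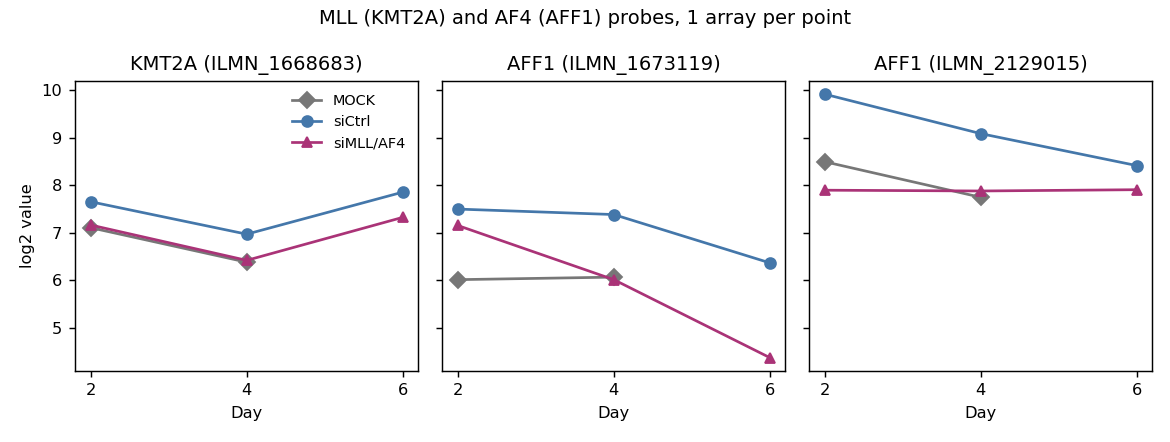
Log2 values (vertical axis) of the KMT2A probe and both AFF1 probes by day (horizontal axis) in MOCK, siCtrl and siMLL/AF4, with 1 array per point and no error bar. The siMLL/AF4 points lie below the siCtrl points on each day, while on day 4 they differ from MOCK by -0.053 to 0.13.

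The main comparison set siMLL/AF4 against siCtrl over the 3 days, to find genes that depend on the fusion. Ranked by the smallest difference over the days, the genes that were higher on every day were led by FCRLA, a B-cell protein related to Fc receptors, which was 14.8-fold higher (log2 3.89 ± 0.36 SE). IFI44, an interferon-induced gene, was 10.1-fold higher (3.34 ± 0.29 SE), and GABARAPL1, a gene of autophagosome formation, was 10.2-fold higher (3.35 ± 0.33 SE). ANXA1, a phospholipid-binding protein of the inflammatory response, was higher by 2.77 ± 0.24 (SE), and GBP2, an interferon-inducible GTPase, by 2.22 ± 0.23 (SE). The genes that were lower on every day included DUSP6, a phosphatase that inactivates ERK, at -2.25 ± 0.26 (SE), CD1A, a lipid antigen-presenting molecule, at -1.87 ± 0.25 (SE), and MYBL2, a transcription factor of the cell cycle, at -2.91 ± 0.63 (SE).

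None of these genes passed the threshold. With limma, 0 of 9096 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.310. At an unadjusted p under 0.05 there were 672 genes, 355 higher and 317 lower, where chance gives 454.8. The 24 genes named by the rule were therefore those with the largest minimum difference over the days. The higher ones also held DYNC1I1 at 3.02, PLEKHG1 at 2.54, NLGN4X at 2.52, RGS1 and SAMD8 at 2.43 each, ENPP2 at 2.35 and ZBED10P at 1.94. Their adjusted p-values (limma) lay between 0.310 and 0.392. The lower ones also held PID1 at -3.13, FAM78A at -2.70, LAIR2 at -2.40, HIVEP2 at -2.13, NOVA1 at -1.93, OSM at -1.89, MED12L at -1.54, AIF1 at -1.49 and RFLNB at -1.34. Their adjusted p-values (limma) lay between 0.353 and 0.609. Of the 10 higher genes measured on both MOCK arrays, 9 were at least 2-fold above MOCK with siMLL/AF4 on both days. Of the 11 lower genes measured there, 8 were below MOCK on both days, 5 of them at least 2-fold. The genes were picked by their values on the same siMLL/AF4 arrays, so these counts against MOCK are no separate evidence. Many of these genes had dim probes in 1 treatment. PLEKHG1, ZBED10P and SAMD8 had means of 1.58, 3.10 and 3.11 in siCtrl. PID1, OSM, MYBL2, FAM78A, NOVA1 and LAIR2 had means of 2.13, 2.42, 2.71, 2.89, 3.22 and 3.36 in siMLL/AF4. All lie under the 25th percentile of the values, 3.48, and CD1A lay near it, at 3.51 in siMLL/AF4. GCNT2 had a larger mean difference than FCRLA, at 4.50 ± 1.64 (SE), but ranged from 1.16 on day 6 to 9.55 on day 4.

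A difference of at least 2-fold in the same direction on all 3 days was seen for 86 genes, 58 higher and 28 lower. Exchanging the 2 siRNA labels on day 2, day 4 or day 6 alone left 34, 25 and 28 such genes. The same sign on all days was seen for 29.2% of genes, where independent differences give 25%. With the labels exchanged on day 2, day 4 or day 6 alone the share was 27.3%, 19.9% and 23.4%. The count of 0 depended on the setting. It became 19 genes (16 higher) when probes under the 70th percentile were left out, 32 (21 higher) with a trended robust variance and 37 (25 higher) with an offset of 64. FCRLA, IFI44, GABARAPL1, NLGN4X and GBP2 passed in each of these 3 settings, with adjusted p-values (limma) from 0.00341 for FCRLA to 0.010 for GBP2 under the stricter filter, and they were the 5 genes that passed with an offset of 16. A further 10 genes passed in each of the 3 settings. They were ANXA1, ENPP2, CMTM8, KLF2, TLR10, SEL1L3 and REEP3, which were higher, and DUSP6, HIVEP2 and ANGPT1, which were lower.

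**Figure D2:**
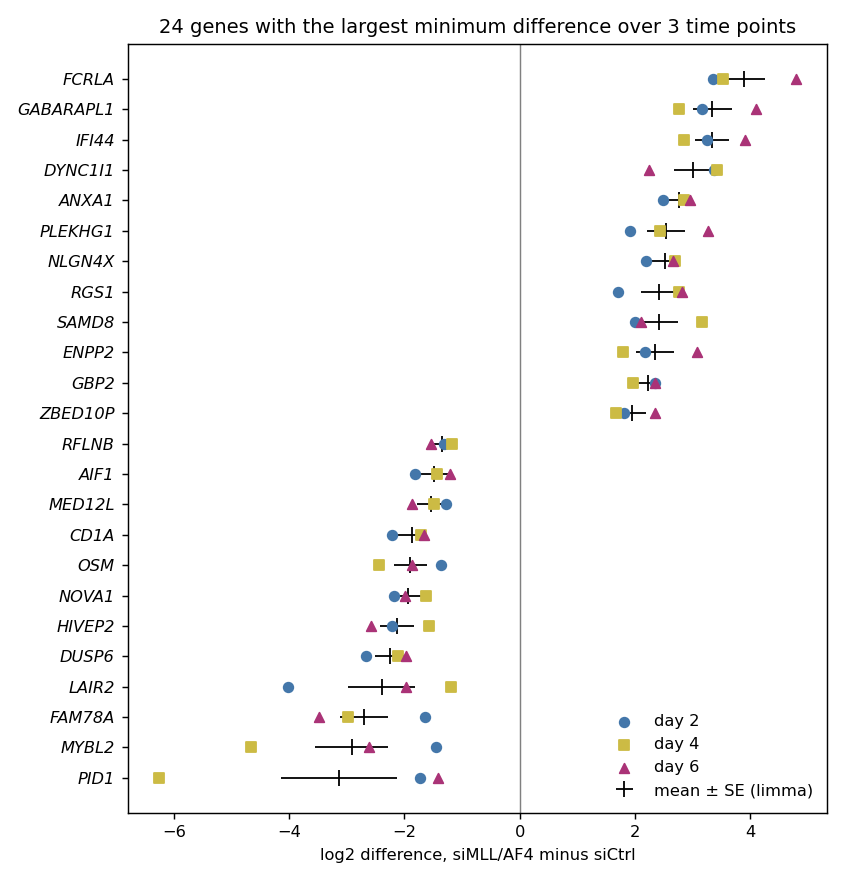
Log2 difference between siMLL/AF4 and siCtrl (horizontal axis) for the 24 named genes (vertical axis), with 1 symbol per day, a tick for the fitted mean and a bar for its SE. The fitted values run from -3.13 for PID1 to 3.89 for FCRLA, and PID1, with the largest SE (1.01), differed by -6.25 on day 4.

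Of the 27 fixed gene lists, 8 passed camera with its preset correlation at an adjusted p under 0.05, 2 higher and 6 lower with siMLL/AF4. Genes of cholesterol synthesis were lower as a list. Of 14 members tested, 12 were lower, with list medians of -0.53, -0.65 and -0.41 on day 2, 4 and 6 (camera, adjusted p = 5.46e-05, and adjusted p = 0.644 with an estimated correlation). MVK, mevalonate kinase, was lower by -1.57, LSS, lanosterol synthase, by -0.88, INSIG1, a sterol sensor that restrains the pathway, by -0.73 and FDPS, farnesyl diphosphate synthase, by -0.69. A second LSS probe was higher, by 0.90, and MVK was higher by 0.46 on day 2. Over the list alone 0 members had an adjusted p under 0.05 (limma), and 2 had an unadjusted one. None of the 8 calls held with an estimated correlation. That test rests on the 2 residual degrees of freedom, and its smallest unadjusted p (camera) was 0.0428, for cholesterol synthesis. The estimated correlation was 0.0077 for this list, under the preset 0.01, but 0.32 for DNA replication and 0.63 for interferon-stimulated genes. The lost calls alone therefore do not show correlated members. Leaving out each day in turn kept the cholesterol list lower, with adjusted p-values (camera) of 0.00140, 0.0104 and 4.88e-04 without day 2, 4 and 6.

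Interferon-stimulated genes rose as a list. Of 22 members tested, 20 were higher with siMLL/AF4 (camera, adjusted p = 3.87e-07, and adjusted p = 0.644 with an estimated correlation), with list medians of 0.11 on day 2, 0.43 on day 4 and 1.99 on day 6. IFI44 was higher by 3.34, IFIT1, an RNA-binding antiviral protein, by 3.14, its relative IFIT2 by 2.29 and RSAD2, an antiviral enzyme, by 2.00. RSAD2 differed by -1.31 on day 2 and by 4.95 on day 4. Counted over all genes 0 members passed (limma), and 3 did when adjusted over the list alone. Without day 6 the list's shift against all genes went from 1.07 to 0.49 and its adjusted p (camera) became 0.0665, and with MOCK as the control on day 2 and day 4 the shift was 0.37 (adjusted p = 0.389). Immediate early genes, which respond to stimulation within minutes, also rose as a list, with 11 of 13 members higher (camera, adjusted p = 8.84e-04, and adjusted p = 0.644 with an estimated correlation). DUSP2 was higher by 2.02, KLF2 by 2.01, ZFP36 by 1.00 and DUSP1 by 0.84. Only 1 member passed when adjusted over the list alone. DUSP2 differed by 5.45 on day 2 and by -0.33 on day 6. Without day 2, 4 and 6 the list's adjusted p (camera) was 0.00473, 0.00301 and 0.143. Its shifts against all genes were then 0.65, 0.66 and 0.50, against 0.69 with all days. With MOCK as the control on day 2 and day 4 the shift was 0.071 (camera, adjusted p = 0.937).

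Known MLL/AF4 target genes were lower in 14 of 21 members (camera, adjusted p = 0.0421, and adjusted p = 0.644 with an estimated correlation), with medians of -0.42, -0.49 and -0.17 on day 2, 4 and 6. CPEB2, a translation regulator, was lower by -1.28, PROM1, the stem-cell surface protein CD133, by -1.25, JMJD1C by -0.98, ARID2 by -0.94 and MEF2C, a transcription factor, by -0.77. RUNX1 differed by -0.42, CDK6 by -0.51, FLT3 by -0.59 and MEIS1 by -0.23. REEP3 and ARID1B went the other way, at 1.98 and 1.26, ARID1B from a dim siCtrl mean of 3.51. Adjusted over the list alone, the 2 members that passed (limma) were these higher ones, and 0 lower members passed, while over all genes 0 members did. The HOXA list was represented by HOXA2 at -1.57, PBX3 at -0.37 and MEIS1 at -0.23 (camera, adjusted p = 0.0445, and adjusted p = 0.644 with an estimated correlation). Of these, 1 passed when adjusted over the list alone, and HOXA2 had a dim mean of 3.58 in siMLL/AF4. The other HOXA genes were not analysed here. Without day 2, 4 and 6 the adjusted p (camera) was 0.0779, 0.271 and 0.0489 for the target list and 0.113, 0.0742 and 0.159 for the HOXA list. The shifts against all genes were then -0.23, -0.17 and -0.34 for the target list and -0.63, -0.85 and -0.68 for the HOXA list, against -0.22 and -0.72 with all days. With MOCK in place of siCtrl on day 2 and day 4, the shift of the MLL/AF4 target list against all genes was 0.40 (camera, adjusted p = 0.253), and that of the HOXA list was -0.12 (camera, adjusted p = 0.937).

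MHC class II genes, which present antigen on B cells, were lower in 8 of 9 members (camera, adjusted p = 0.0445, and adjusted p = 0.644 with an estimated correlation). HLA-DPA1 was lower by -1.60, HLA-DOA by -0.97 and CD74, the invariant chain, by -0.59, while HLA-DQB1 was higher by 0.41 with day values from 2.46 to -2.26. Adjusted over the list alone, 1 member passed. DNA replication genes were lower in 23 of 25 members (camera, adjusted p = 0.0445, and adjusted p = 0.778 with an estimated correlation), and their medians were 0.27 on day 2, -0.34 on day 4 and -0.32 on day 6. CDC6, which loads the replicative helicase, was lower by -1.11, POLE by -0.81, CCNE1 by -0.70 and TK1 by -0.37. Mitosis genes were lower in 20 of 28 members (camera, adjusted p = 0.0445, and adjusted p = 0.644 with an estimated correlation). MKI67, the Ki-67 proliferation marker, differed by -1.25, -1.15 and -1.12 on day 2, 4 and 6, whereas PLK1 was higher by 1.43 on day 2 and lower by -4.32 on day 6. In both lists 0 members passed when adjusted over the list alone (limma), with 2 and 1 members at an unadjusted p under 0.05. Without day 2, 4 and 6 the adjusted p (camera) was 0.00140, 0.681 and 0.293 for DNA replication, 0.114, 0.302 and 0.120 for mitosis, and 0.0499, 0.0742 and 0.143 for MHC class II. The shifts against all genes were then -0.36, -0.11 and -0.16, -0.21, -0.19 and -0.23, and -0.55, -0.52 and -0.35 for these lists in the same order, against -0.21, -0.21 and -0.40 with all days. With MOCK as the control the adjusted p (camera) was 0.805, 0.890 and 0.0135. The MHC class II medians against MOCK on day 2 and day 4 were -0.63 and -0.63 with siMLL/AF4, over 7 members. With siCtrl they were -0.55 and -0.56, and the medians of siMLL/AF4 minus siCtrl over these members were -0.33 and -0.37. Medians of such differences do not add up, so the part shared by both siRNA treatments cannot be read from them.

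**Figure D3:**
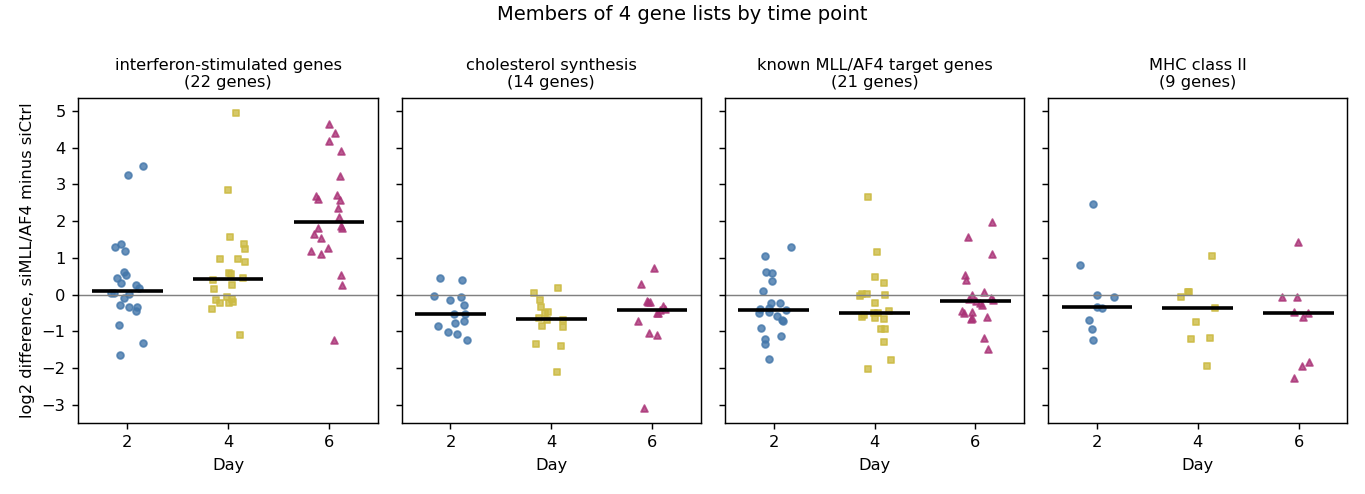
Log2 difference between siMLL/AF4 and siCtrl (vertical axis) by day (horizontal axis) for the tested members of 4 gene lists, with 1 point per gene and a bar at the median. The median of the interferon list goes from 0.11 on day 2 to 1.99 on day 6, and that of the cholesterol list lies between -0.65 and -0.41.

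The other 19 lists did not pass. Among genes of the B lineage, B-lineage transcription factors were lower in 9 of 12 members (camera, adjusted p = 0.227), with IKZF1 at -0.70 and SPIB at -0.67. B-cell receptor and surface genes were higher in 8 of 11 (camera, adjusted p = 0.255), with CD79A at 0.74. Stem and progenitor genes were lower in 9 of 12 (camera, adjusted p = 0.130), with CSPG4 at -2.05 and PROM1 at -1.25 but CD34 at 2.02. CD34 was dim in siCtrl, with a mean of 3.32. Markers of other blood lineages did not pass either. Myeloid markers were higher in 4 of 7 (camera, adjusted p = 0.591), with LYZ at 1.07, T and NK cell markers were higher in 3 of 5 (camera, adjusted p = 0.807), with GZMA at -1.50, and the erythroid list held a single tested gene, HBG2, at -0.55. In the BCL2 family list (camera, adjusted p = 0.983) the pro-apoptotic BMF and PMAIP1 were higher by 1.05 and 1.01, while the pro-apoptotic BBC3 was lower by -0.98. Among p53 targets (camera, adjusted p = 0.362) GADD45A was higher by 0.96 and DDB2 lower by -0.86. Ribosomal proteins had a median of -0.031 (camera, adjusted p = 0.818), and genes of ribosome biogenesis one of -0.11 (camera, adjusted p = 0.362). The remaining lists covered complex members of MLL and AF4, G1 cyclins, heat shock, NF-kB targets, MHC class I, glycolysis, adhesion, polycomb and RNA interference, with adjusted p-values (camera) from 0.362 to 0.983. The median, the mean and the test differed in sign for the BCL2 family, G1 cyclin, T and NK cell, NF-kB, glycolysis and polycomb lists.

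On each day taken alone there was no replicate and no test. A difference of at least 2-fold was seen for 1319 of 9096 genes on day 2, 675 of them higher with siMLL/AF4, for 903 on day 4, 497 higher, and for 1726 on day 6, 724 higher. The largest differences on day 2 were those of IFT43 at 8.84, BBOF1 at 8.73, ETV3 and HCG27 at 5.76 each and CD40 at 5.57, and of RIMBP3 at -5.67, H4C2 at -5.64, PLPP2 at -5.53, FAM184A at -4.97 and BMP8B at -4.93. On day 4 they were those of GCNT2 at 9.55, ELOVL3 at 7.60, TIGD6 at 5.54, GIMAP4 at 5.05 and RSAD2 at 4.95, and of EPHA1 at -6.46, PID1 at -6.25, GPATCH8 at -5.65, PGAP1 at -5.50 and ALG2 at -4.98. On day 6 they were those of BHLHE40 at 5.81, RNA28SN5 at 5.35, ADAMTS6 at 5.24, POU3F2 at 5.14 and KCNG2 at 5.03, and of ANAPC7 at -6.37, GCAT at -6.21, LINC02985 at -5.86, S100A6 at -5.57 and EHMT2 at -5.52. Several rested on a value near the lowest on the arrays, -3.21, as for IFT43, BBOF1, GCNT2, ELOVL3 and EPHA1. On the siMLL/AF4 array of day 6, the probe of 28S ribosomal RNA (RNA28SN5) stood at 11.86, against 6.51 in siCtrl, while it ranged from 10.15 to 13.74 on the 6 older arrays. This probe also differed between siCtrl and siMLL/AF4 on day 2 (13.74 and 10.89) and, the other way, on day 4 (10.26 and 13.06). With an offset of 64 the counts were 391, 149 and 567 genes on day 2, 4 and 6.

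Against the spread of random lists matched on expression, cholesterol synthesis stood at the 0.19, 0.00 and 0.52 percentile on day 2, 4 and 6. Interferon-stimulated genes stood at the 53.5, 99.9 and 100 percentile, and MLL/AF4 target genes at the 0.31, 0.00 and 11.6 percentile. Ribosomal proteins went from the 8.33 percentile on day 2 to the 99.96 percentile on day 4 and the 69.9 percentile on day 6. These percentiles describe 1 pair of arrays each.

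Whether the effect of the knock-down grew with its duration was tested as a slope per day. The interferon list was the one that passed among 27, with 21 of 22 members having a positive slope (camera, adjusted p = 2.94e-08, and adjusted p = 0.933 with an estimated correlation). Its mean slope exceeded that of all genes by 0.49 per day, and its medians of 0.11, 0.43 and 1.99 put most of the rise on day 6. The day 6 pair was on the newer array version, its siMLL/AF4 array correlated least with the older arrays (0.831), and its siCtrl array stood at 6.51 on the 28S ribosomal RNA probe. List tests in this and the following comparisons were added after seeing the data. No single gene passed (limma, 0 of 9096 genes, smallest adjusted p = 0.284), with 1096 genes at an unadjusted p under 0.05 where chance gives 454.8. The steepest positive slopes were those of RIMBP3 at 2.20, KCNG2 at 2.05, RNA28SN5 at 2.05, PLPP2 at 1.96 and FAM184A at 1.78 per day. The steepest negative ones were those of CALB2 at -2.26, BBOF1 at -1.98, EHMT2 at -1.88, ANAPC7 at -1.77 and RUNX3, a lymphoid transcription factor, at -1.76 per day. The fit left 1 residual degree of freedom, and the stricter filter called 435 genes, the trended robust variance 386 and the offset of 64 called 346.

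Changes between day 2 and day 4, averaged over both siRNA treatments, were tested on the 4 siRNA arrays of the older version, because day and array version could not be separated on day 6. Cholesterol synthesis fell as a list with day, with 13 of 16 members lower (camera, adjusted p = 0.0275, and adjusted p = 0.806 with an estimated correlation). The list medians of the change from day 2 to day 4 were -0.43 in siCtrl and -0.88 in siMLL/AF4. When adjusted over the list alone, 0 members passed (limma). MLL/AF4 target genes fell as a list, with 17 of 22 members lower (camera, adjusted p = 0.0275, and adjusted p = 0.806 with an estimated correlation), with medians of -0.22 and -0.46. DNA replication genes were lower in 21 of 25 members (camera, adjusted p = 0.0480, and adjusted p = 0.806 with an estimated correlation), but their medians were 0.025 in siCtrl and -0.72 in siMLL/AF4, so the values do not show a change shared by both treatments. The slope of the difference between treatments over the 3 days did not pass for this list (camera, adjusted p = 0.249). With the mean of probes the adjusted p (camera) was 0.0704 for the target list and 0.0542 for DNA replication. No gene passed (limma, 0 of 10855 genes, smallest adjusted p = 0.575), and 893 had an unadjusted p under 0.05 where chance gives 542.8. The highest slopes per day were those of SSX4B at 2.20, C19orf73 at 2.14, ZNF526 at 2.10, IFT43 at 2.08 and DHRS9 at 2.07, and the lowest those of EPHA1 at -2.30, SMPDL3B at -2.19, WWC2 at -2.13, ATRNL1 at -2.04 and SMPD1 at -2.01. The stricter filter called 195 genes, the trended robust variance 306 and the offset of 64 called 352.

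The control siRNA was compared with MOCK to see what siRNA delivery itself was associated with. Known MLL/AF4 target genes rose as a list in siCtrl, with 19 of 21 members higher (camera, adjusted p = 1.58e-06, and adjusted p = 0.536 with an estimated correlation). Their medians were 0.95 on day 2 and 0.65 on day 4, and 10 members passed when adjusted over the list alone. CPEB2 lay above MOCK by 1.42 on day 2, JMJD1C by 1.38 and MEF2C by 1.23. With siMLL/AF4 the list medians against MOCK were 0.23 and 0.20. This comparison shares its siCtrl arrays with the knock-down comparison, so a chance deviation of these arrays would move the list in opposite directions in both. The other 25 lists did not pass camera, the next being genes of RNA interference, myeloid markers and MHC class I (camera, adjusted p = 0.102 each). With fry, 3 lists passed, the MLL/AF4 target, mitosis and MHC class I lists (adjusted p = 0.0395 each). MHC class I genes were lower in 10 of 12 members, and the RNA interference machinery was higher in 8 of 11.

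No gene passed between siCtrl and MOCK (limma, 0 of 8886 genes, smallest adjusted p = 0.210), and 1770 had an unadjusted p under 0.05, where chance gives 444.3. Of these, 1043 were higher and 727 lower in siCtrl. Without day 2 and without day 4, with 1 MOCK array left each time, the number was 477 and 566. A difference of at least 2-fold was seen for 1829 genes on day 2 and 1094 on day 4. On the same genes the difference between siMLL/AF4 and siCtrl reached 2-fold for 1201 and 786. The highest fitted differences were those of HAUS6 at 3.81 ± 1.20 (SE), ZNF610 at 3.44 ± 0.39, PMS1 at 3.42 ± 1.05, MEGF10 at 3.17 ± 0.53 and MOB1B, a Hippo pathway gene, at 3.11 ± 0.32. The lowest were those of IFT43 at -4.11 ± 2.04 (SE), GCNT2 at -3.61 ± 1.78, ETV3 at -3.20 ± 1.32, DOK3 at -3.15 ± 0.85 and BBOF1 at -2.94 ± 1.91. MOB1B lay above MOCK by 3.70 and 2.70 in siCtrl and by 3.07 and 2.92 in siMLL/AF4.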

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

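The tests of explanations in this part were chosen after the results were seen, except the splits of the samples, which were planned, and the list test of the slope was added after seeing the data.

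The interferon-stimulated list differed between time points: its siMLL/AF4 minus siCtrl difference changed by 0.486 (log2) per day more than that of all genes, by the list test of the slope (camera, adjusted p = 2.94e-08, and adjusted p = 0.933 with an estimated correlation). The pattern weighed is the higher level of this list with siMLL/AF4. Whether the day 6 arrays alone carry the pattern stays open: without them the adjusted p (camera) was 0.0665, while the day 4 median stood at the 99.9 percentile of random lists. That percentile takes no account of correlated members (estimated correlation 0.63). Ribosomal proteins, a list that did not pass, stood at the 99.96 percentile on the same day, so it decides little. Sensing of the siMLL/AF4 siRNA as foreign RNA and loss of the fusion cannot be told apart, because the labels give a single siRNA treatment against the fusion. In it the list median lay above MOCK by 0.073 on day 2 and by 0.30 on day 4.

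The second pattern was that MLL/AF4 target genes and AFF1 were higher in siCtrl than in MOCK and lower in siMLL/AF4 than in siCtrl. A shift by probe level alone is argued against by random lists matched on mean expression. The target list in siCtrl minus MOCK stood at the 100 percentile of them on both days (medians 0.95 and 0.65, highest of 10000 random lists 0.67 and 0.54). The list was picked for this same difference, so a high percentile is no separate evidence that it rose. Random lists also cannot address an array effect that acts on a class of genes. That the siCtrl arrays alone were out of line was weighed by the target list in siMLL/AF4 minus MOCK. It stood at the 80.7 and 93.0 percentile of such random lists on day 2 and day 4 (medians 0.23 and 0.20). Of 21 members, 18 and 13 lay above MOCK on these days. A deviation of the siCtrl arrays alone would allow this. Loss of the fusion would allow it only with a further difference between MOCK and both siRNA treatments. Such a difference was not tested, so these explanations cannot be told apart. Over all genes, siMLL/AF4 minus MOCK and siCtrl minus MOCK on different days, which share no array, correlated at r = 0.386 and 0.299, and at 0.628 and 0.538 over the brighter 4443 (genes are not independent replicates), which goes against a deviation of the siCtrl arrays alone but could come from the MOCK arrays, which correlated with each other at 0.979 (Spearman, bright probes). An effect of siRNA delivery, or of the pulse without siRNA, on these genes stays open and was not tested, and part of the fall with siMLL/AF4 could come from the shared siCtrl arrays, since the target list shifted by 0.40 against MOCK.

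The third pattern was that the siMLL/AF4 array of day 6 correlated least with the other arrays. Array version as the whole cause is argued against by the siCtrl array of day 6, on the same version, which correlated better with 6 of 6 older arrays. Over bright probes the margin was small for the siMLL/AF4 array of day 4 (0.878 against 0.875). The day 6 arrays correlated with each other at 0.939 over bright probes, so version or day as part of the cause stays open. Noise of dim probes is argued against by bright probes, where the median correlation with the older arrays was 0.816, against 0.867 for siCtrl on day 6 and 0.916 to 0.948 among the older arrays. RNA or labelling quality of that sample cannot be told apart from the treatment with 1 array per treatment and day. Its 28S ribosomal RNA probe (11.86) lay within the range of the older arrays (10.15 to 13.74), and siCtrl on day 6 lay outside it (6.51). That range is wide because the probe also differed within older days. On day 2 it stood at 13.74 in siCtrl and 10.89 in siMLL/AF4, and on day 4 at 10.26 and 13.06. A value within the range therefore says little about quality. A larger effect of the longer knock-down stays open as well.

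The 6 siRNA arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With 0 genes called by limma in the real split, 10 of 10 splits gave as many, and the highest other value was 0. Any split gives at least 0, so this count could not separate the real split from the others. At an unadjusted p under 0.05 the real split gave 672 genes, 3 of 10 splits gave as many, and the highest other value was 942. With time point as a block, that value comes from 2 splits that are the same contrast, in which only the day 6 pair is parted. Parting only the day 2 pair (607 genes) or only the day 4 pair (213 genes) likewise counts 1 contrast as 2 splits. For lists called by camera the real split gave 8, 1 of 10 splits gave as many, and the highest other value was 5. The 3 other splits that part the pair of every day gave 221, 322 and 401 genes at an unadjusted p under 0.05 and 2, 1 and 5 lists.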

How the results depend on the processing

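Chosen after seeing the data were the offset of 16, Null entries tested at the floor, MOCK as control, the stricter filter joined with the trended robust variance, camera between siCtrl and MOCK, and, for lists, the common median, the mean of probes, the 70th percentile filter and the mean control. Genes past the threshold between siMLL/AF4 and siCtrl (0 in the main setting) numbered 5 with an offset of 16, 37 with an offset of 64, 19 with the 70th percentile filter, 32 with the trended robust variance and 47 with both of these, and 0 under the other settings run. For the change of the effect with day the first 4 settings gave 167, 346, 435 and 386 genes, and for the change with day 58, 352, 195 and 306, in place of 0. The cause was not tested. Lists called (8) numbered 5 with an offset of 16, 4 with the floor, 5 with no filter, 3 with the mean of probes, 4 with the mean of siCtrl and MOCK as control, 5 with Null entries tested, 3 with MOCK as control, 0 with an estimated correlation, 0 with fry, and 2 to 5 when a time point was left out. Leaving out the estimated correlation and fry, under which 0 calls held, there were 120 values of the 8 called lists. Of these, 74 kept direction and side of the threshold, 43 lost the call and 3 reversed. The reversed ones were the target list at 0.045 with the mean control and at 0.40 with MOCK, and mitosis at 0.0076 with MOCK. Camera called 1 list between siCtrl and MOCK, where 0 genes passed in any setting. Genes at 2-fold numbered 849 on day 2 and 478 on day 4 with an offset of 16, and 391, 149 and 567 on day 2, 4 and 6 with an offset of 64.

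KMT2A was -0.47 and -0.37 with offsets of 16 and 64. With MOCK as control and day 6 left out, KMT2A was 0.048, AFF1 0.54 at ILMN_1673119 and -0.23 at ILMN_2129015, MED12L 0.72, MEIS1 0.066, PLK1 0.30, KIF23 0.17 and CENPE 0.37. Without day 6, which equals keeping only the older version, CCNE1 was 0.25 and PLK1 0.60, and over the left-out days CCNE1 ranged from -1.48 to 0.25, PLK1 from -2.28 to 0.60 and HLA-DQB1 from -0.61 to 1.75. HLA-DQB1 was -0.072 and -0.096 with offsets of 16 and 64 and -0.37 with the floor. Of 1048 values of 56 named genes, 974 were unchanged in direction and call, 60 gained a call and 14 reversed. The cause of the reversals was not tested. The change with day could not be run without day 2 or day 4, since it needs both, and day 6 was not in it. Signal near background limits the dim probes.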

Other observations

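The values in this part were picked after the results were seen, and no explanation was tested for them. NQO1, a quinone reductase, GCLM, a subunit of the enzyme of glutathione synthesis, and PIR, an iron-binding nuclear protein, were higher with siMLL/AF4 by 1.74, 1.52 and 1.67. They were chosen after their values were seen, did not pass in the main setting and passed limma in a setting with a trended robust variance (adjusted p = 0.00809, 0.00809 and 0.0217). Also chosen after their values were seen, TLR10, a Toll-like receptor, was higher by 1.91, and ANGPT1, a secreted ligand of the receptor TIE2, was lower by -1.92 (adjusted p = 0.00437 each in that setting, limma). CD93, a surface glycoprotein, was lower by -1.88 (adjusted p = 0.0364 in that setting, limma). In the main setting 0 genes passed limma, with 672 at an unadjusted p under 0.05.

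Between day 2 and day 4, siCtrl minus MOCK correlated across genes at r = 0.412 over all 8886 and 0.734 over the brighter 4443, and siMLL/AF4 minus siCtrl at 0.0978 and 0.0864. The latter correlated at 0.0179 and -0.0604 between day 2 and day 6 and at 0.180 and 0.320 between day 4 and day 6, over all and over the brighter genes. The day 6 difference between siMLL/AF4 and siCtrl correlated with siCtrl minus MOCK at 0.119 and 0.288 for day 2 and at 0.148 and 0.339 for day 4. The day 4 difference correlated with siCtrl minus MOCK of day 2 at -0.113 and -0.242, and the day 2 difference with that of day 4 at -0.0637 and -0.108. These pairs share no array, and genes are not independent replicates.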
